A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

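Total RNA from Schizosaccharomyces pombe was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols, with 2 arrays for cells overexpressing Atf1 and 2 for cells with the empty vector. Groups and replicate numbers were taken from the sample titles. The deposited values were log2 probe set summaries, 1 per probe set and array, as judged from their range of 1.46 to 14.0. The summarisation, background correction and between-array normalization behind these log2 values are not given in the sources used here. Scanner files were not used here.

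The deposited table held 10928 probe sets. The platform annotation named 5538 of them and left 5224 unnamed, beside 166 control probe sets. Names were matched to the RefSeq gene table of assembly ASM294v3, used for names, gene lengths, gene order and distance to chromosome ends only. Of the S. pombe probe sets, 2914 matched by identifier and 3 by symbol, 113 symbols were updated, and 20 with several genes were left unnamed. S. cerevisiae probe sets numbered 2593 and 8 further named probe sets were assigned to neither yeast here. For genes with several probe sets, the one with the highest mean was kept, giving 2899 genes and leaving out 18 probe sets. Of the unnamed probe sets, 2176 lay above background and were not analysed here.

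Array medians over S. pombe probe sets were 6.81 and 6.70 in the control and 6.97 and 6.98 under overexpression, a range of 0.28. Since this exceeded the tolerance of 0.1 fixed before the data were examined, values were quantile normalized over S. pombe probe sets. Quantile normalization left 50 genes with an SD of exactly 0 in the control group and 26 in the overexpression group. The 95th percentile of S. cerevisiae probe sets served as background, at 3.06, 3.16, 2.74 and 2.69 on the deposited scale, and a gene was kept if it exceeded it on at least 2 of the 4 arrays. This left 2857 genes and removed 42. A gene at or below background on both arrays of a group has only a bound, given as "at least N-fold" from the bright group's mean against the mean, over the dim group's arrays, of the higher of background and the gene's own value.

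Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with Benjamini-Hochberg adjustment over all genes, at an adjusted p under 0.05. Gene lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 22 lists. They were also tested with an estimated correlation and with fry. The latter asks whether a list's genes move one way on balance without comparing them with other genes. With 2 arrays per group, camera with an estimated correlation has few residual degrees of freedom and little power. The test, the 24 lists, the alternatives and the rule for named genes were fixed before the data were examined, except where said otherwise. Of these lists, the Tf2 transposon list had 0 measured members and the phosphate list 2. The subtelomeric list held genes within 100 kb of a chromosome end.

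The rule named atf1, pcr1, sty1 and wis1, the 8 largest fitted rises and 8 largest fitted falls that passed with no overlap between groups, and up to 3 members of each list with the smallest p. A further 62 genes, among them yox1, plo1, cut2, ght1, isp5, mcp60 and mei4, were chosen after their values were seen, as members of short counts or of families described. Alternatives were other scalings, background filters, variance models, probe set rules, a pseudocount of 16, a replicate block, a looser threshold, other set tests and leaving out each array in turn. The deposited values without renormalization and a loess correction for gene length were added after the data were seen. With 1 array left out, the lone array was assumed to vary like the other group.

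The method was tested on simulated data for this comparison, with 200 of 2857 genes changed in each of 5 runs. It recovered 38% of genes changed 1.5-fold and 68.2% of genes changed 2-fold, and 3.15% of the calls were false. The simulated errors were normal and independent between genes, with SDs drawn at random across genes and no shift between the groups as a whole. The share of false calls in the real data may therefore differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.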

Results

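Messenger RNA levels were measured in the fission yeast Schizosaccharomyces pombe on Affymetrix yeast arrays, which carry probe sets for both S. pombe and the budding yeast Saccharomyces cerevisiae. Cells overexpressing Atf1 were compared with cells carrying the empty vector, and each group had 2 arrays, which the labels call biological replicates. Atf1 is a bZIP transcription factor of the Sty1 stress-activated MAP kinase pathway. After naming and a background filter, 2857 S. pombe genes were tested. Replicate arrays correlated across genes with Pearson r = 0.992 in the control and 0.993 in the overexpression group, against 0.973 to 0.983 between groups. The precision of every value below is limited by 2 arrays per group.

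The atf1 transcript itself (SPBC29B5.01) was higher on both overexpression arrays than on both control arrays. Its deposited log2 values were 6.01 and 6.19 in the control and 6.94 and 7.47 under overexpression, a difference of 1.10. Where the atf1 probe set lies relative to the overexpressed copy was not known, so it may not read all of the overexpression. After normalization the level was 6.27 ± 0.20 (SD, n = 2) in the control and 7.10 ± 0.38 (SD, n = 2) under overexpression, a log2 difference of 0.83 ± 0.20 (SE), or 1.78-fold (limma, adjusted p = 0.0273). The adjusted p was 0.128 without control replicate 1, 0.0821 without control replicate 2 and 0.137 without overexpression replicate 2, with log2 differences of 0.67, 0.93 and 0.58. Of its partners, pcr1, which encodes the bZIP protein that pairs with Atf1, had a log2 difference of -0.45 ± 0.18 (SE) with an adjusted p of 0.115. The MAP kinase gene sty1 differed by 0.01 (adjusted p = 0.973) and the MAP kinase kinase gene wis1 by 0.03 (adjusted p = 0.890). These last values changed sign under some settings.

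Across all genes, 607 of 2857 passed an adjusted p of 0.05 in limma, of which 292 rose and 315 fell. The fitted change was at least 2-fold for 50 of them, 30 higher and 20 lower. Of the 30, 4, among them alp7 and tas3, were not above background on either control array and had lower bounds under 2-fold. The gene with the largest rise was fhn1 (SPBC1685.13), a membrane protein gene, at 3.46 ± 0.27 (SD, n = 2) in the control and 5.63 ± 0.02 (SD, n = 2) under overexpression, 4.51-fold higher (limma, adjusted p = 0.00232). It was followed by mug86 (3.42-fold) and cdc18 (3.24-fold), which encodes a replication licensing factor. The alcohol dehydrogenase gene adh4 (2.81-fold), the G1/S cyclin gene cig2 (2.80-fold) and the mating gene ste7 (2.73-fold) were also among the 8 largest fitted rises. So were alp7, a microtubule protein gene, and tas3, which encodes a subunit of the RNA-induced transcriptional silencing complex RITS. Because of their background level in the control, alp7 was at least 1.35-fold and tas3 at least 1.73-fold higher, and their place in the order is not known.

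The gene with the largest fitted fall was num1 (SPBC216.02), a cortical anchor of dynein in meiosis, at 6.27 ± 0.03 (SD, n = 2) in the control and 4.78 ± 0.14 (SD, n = 2) under overexpression, 2.81-fold lower (limma, adjusted p = 0.00349). The histone H3 lysine methyltransferase genes clr4 and set7 were 2.53-fold and 2.38-fold lower. The meiotically upregulated gene mug116 was 2.53-fold lower. For mug62 the overexpression arrays were not above background, and it was at least 2.20-fold lower, so its place in the order is not known. After normalization, background stood at 3.25 and 3.33 in the control and lower, at 2.67 and 2.63, under overexpression. The control mean of mug62 was 3.79, so its bound and the falls of other dim genes may partly hold this difference in background. The meiotic recombinase gene dmc1 was 2.31-fold lower, aph1, a hydrolase gene, 2.29-fold lower and the protein kinase gene ppk38 2.24-fold lower.

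Groups did not overlap for 66.4% of genes, against 33.3% by chance for 2 arrays against 2. Without control replicate 1 the number of genes passing dropped to 53, without control replicate 2 to 68 and without overexpression replicate 2 to 355, when 25 genes changed at least 2-fold. Without control replicate 1 or 2, only 1 and 2 of the 22 mating genes rose and 1 and 2 of the 21 meiotic genes fell, whereas 4 of the 14 G1/S genes rose in each of these fits, as with all arrays. Among the genes named, fhn1, mug86, cdc18, adh4, cig2, ste7, num1, clr4, set7, ppk38, cdc22, yox1, hta2, hhf2, isp4, rgs1, ght3, eno102, gal1, hsp9, zym1 and psm3 passed in each of the 4 fits that left out 1 array. The other named genes that passed with all arrays lost their call in at least 1 of those fits. For hsp9 the arrays of each group had the same normalized value, so these fits could not show its spread. The balance of directions followed the scaling: with the deposited values, an alternative added after the data were seen, the median of all genes lay 0.27 higher under overexpression on the log2 scale and 903 genes rose while 116 fell.

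**Figure D1:**
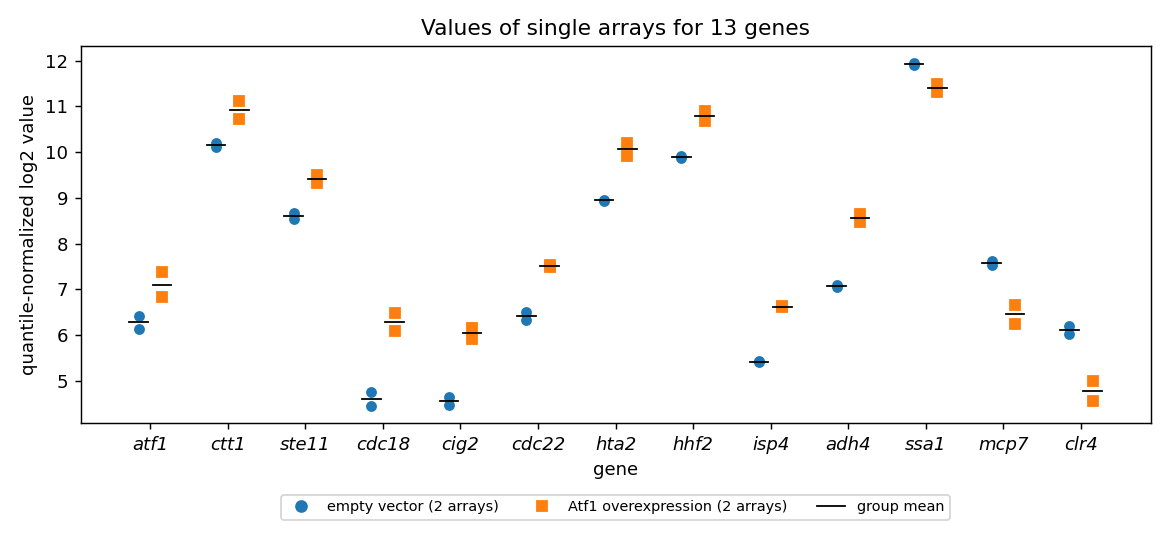
Quantile-normalized log2 values (vertical axis) of single arrays for 13 genes (horizontal axis), with circles for the 2 empty vector arrays, squares for the 2 Atf1 overexpression arrays and lines for group means. The atf1 means were 6.27 and 7.10, those of cdc18 4.59 and 6.29, and those of clr4 6.11 and 4.77.

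The added control transcripts and ribosomal RNA probe sets also differed between the groups, with no overlap of the class means. Hybridization controls were lower under overexpression on all 27 probe sets, with mean log2 values of 11.9 in the control and 10.9 under overexpression. These probe sets read the bioB, bioC, bioD and cre transcripts several times each, and their shifts ran from -1.61 to -0.17. Poly-A controls at the 5′ end were higher, with class means of 3.06 and 4.61, although 6 of their 12 probe sets were at background on both control arrays, so that the mean shift was at least 1.27. Poly-A probe sets from the middle of the transcripts, all above background on every array, were higher by a mean of 1.22, and the 7 S. pombe ribosomal RNA probe sets were lower by a mean log2 of -0.66. This difference ran parallel with every gene group below. Genes that rose were longer, with a median gene length of 2083 bp against 1875 bp for all tested genes, and those that fell were shorter, at 1554 bp.

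**Figure D2:**
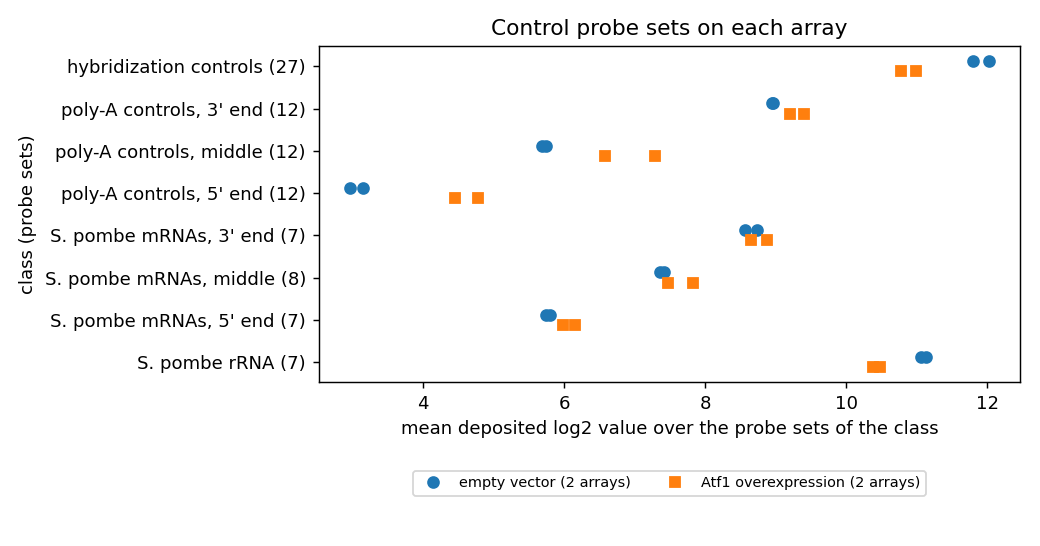
Mean deposited log2 value (horizontal axis) of each class of control probe sets (vertical axis, number of probe sets in brackets) on each array, with circles for the 2 empty vector arrays and squares for the 2 Atf1 overexpression arrays. Hybridization controls averaged 11.9 and 10.9 in these groups, and poly-A controls at the 5′ end 3.06 and 4.61, with 6 of those 12 probe sets at background in the control.

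Of 10 histone genes, 9 rose and none fell, with a median log2 difference of 0.72. The exception was pht1, which encodes the variant H2A.Z, at -0.01 (adjusted p = 0.956). The rises included hta2 (1.12 ± 0.10 SE, adjusted p = 0.00232), hhf2 (0.90 ± 0.09 SE, adjusted p = 0.00253) and hta1 (0.75 ± 0.08 SE, adjusted p = 0.00345). Of 14 genes of the G1/S wave driven by the MBF factor, 4 rose, none fell and 10 did not pass, and the median was 0.45, or 0.21 without control replicate 1. These were cdc18 (1.70), cig2 (1.48), yox1 (1.41), a repressor of that wave, and cdc22 (1.09), which encodes the large subunit of ribonucleotide reductase. Adjusted over the list alone, 9 histone genes and 6 G1/S genes passed. With median centring 8 histone and 7 G1/S genes rose, and with the deposited values 9 and 12. Both lists were called upward by camera, with adjusted p values of 1.46e-06 and 0.000542, and neither call held with an estimated correlation (adjusted p = 0.462 with an estimated correlation for each). The histone genes have near-identical copies, so the values of single copies are uncertain. Without control replicate 1, 3 histone genes passed, and without control replicate 2, 4 did.

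Of 25 genes of mitosis and its control, 6 rose, none fell and 19 did not pass, with a median log2 difference of 0.29, or 0.44 without control replicate 2. Among them were mid1 (0.99), whose product positions the division ring, spo12 (0.92), the polo kinase gene plo1 (0.90), the type II myosin gene myp2 (0.72) and the securin gene cut2 (0.68). The mitotic cyclin gene cdc13 stood at -0.01 (adjusted p = 0.947), with a positive sign in the deposited values, and the phosphatase gene cdc25 at 0.63 (adjusted p = 0.0677). Adjusted over the list alone, 7 genes rose, and over all genes 11 rose with median centring and 17 with the deposited values. The list was called by camera (adjusted p = 0.0182; adjusted p = 0.462 with an estimated correlation), and not without overexpression replicate 1 (adjusted p = 0.0678) or replicate 2 (adjusted p = 0.0622). No member passed without control replicate 1 or overexpression replicate 2, while 2 passed without control replicate 2 and 1 without overexpression replicate 1. Of 6 measured cell separation genes, mid2 fell by 0.85 on the log2 scale and the rest did not pass. The median of that list was -0.50 and its mean -0.16, and it was not called (adjusted p = 0.386). Adjusted over the list alone, 1 of these genes rose and 2 fell. Over all genes, 2 cell separation genes rose and 1 fell with the deposited values, with a list median of -0.04. With median centring 2 rose and 1 fell as well, with a list median of -0.26.

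Of 19 genes of the Sty1 pathway, 4 rose and none fell: atf1 itself, the MAP kinase kinase kinase genes win1 (0.90) and wis4 (0.50), and the phosphatase gene pyp1 (0.48). Since atf1 was overexpressed by design, any call of this list counts that gene too, and the list was not tested without it. Adjusted over the list alone the same number, 4, passed, while 8 rose with median centring, 11 with the deposited values and none in a fit without trend. The median was 0.24, or 0.13 without control replicate 1, when 1 gene passed; none passed without control replicate 2 and 1 without overexpression replicate 2. Camera called the list (adjusted p = 0.0497; adjusted p = 0.462 with an estimated correlation), though not without control replicate 1 (adjusted p = 0.0801) or overexpression replicate 2 (adjusted p = 0.138), nor with median centring (adjusted p = 0.0563), the deposited values (adjusted p = 0.128), the length correction (adjusted p = 0.0858) or a fit without trend (adjusted p = 0.0857). Of 21 stress targets of Sty1 and Atf1, 4 rose, 5 fell and 12 did not pass, and 7 rose and 5 fell adjusted over the list alone. The catalase gene ctt1 (0.77 ± 0.12 SE, adjusted p = 0.00826), the mating regulator gene ste11 (0.82 ± 0.10 SE, adjusted p = 0.00405), lsd90 (0.48) and hsp9 (0.44) rose. The metallothionein gene zym1 (-0.57 ± 0.05 SE, adjusted p = 0.00232), the trehalose phosphatase gene tpp1 (-0.54), rds1 (-0.52), the glutaredoxin gene grx1 (-0.37) and the small heat shock gene hsp16 (-0.23) fell. In the deposited values hsp16 stood at 0.036. For hsp9 and hsp16 the SD was exactly 0 in both groups after quantile normalization. The hsp16 value in the control, 13.57, was also the hsp9 value under overexpression. Both changes thus reflect ranks, and their spread between arrays is not known. The glycerol phosphate dehydrogenase gene gpd1 (0.27, adjusted p = 0.0774), fbp1 (0.59, adjusted p = 0.0557), pyp2 (0.24, adjusted p = 0.322) and srk1 (-0.07, adjusted p = 0.746, positive in the deposited values) did not pass. The target list had a median of 0.22 and was not called (adjusted p = 0.370). Without overexpression replicate 1, 10 targets rose and 5 fell, the median was 0.41 and the list was called upward (adjusted p = 0.0435; with all arrays adjusted p = 0.687 with an estimated correlation), whereas without overexpression replicate 2, 7 rose and 5 fell with a median of 0.052. Without control replicate 1, 1 rose and 1 fell, and without control replicate 2, 2 rose and 1 fell with a median of 0.15. With the deposited values 10 targets rose and 4 fell, and with median centring 5 rose and 4 fell.

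Of 13 heat shock genes, 6 fell, 1 rose and 6 did not pass, both over all genes and adjusted over the list alone, with a median of -0.23, or -0.15 without overexpression replicate 1. The cochaperone gene wos2 (-0.68), the chaperonin gene hsp10 (-0.54) and the Hsp70 gene ssa1 (-0.53) fell, and the mitochondrial chaperonin gene mcp60 (0.51) rose. Camera called the list downward (adjusted p = 0.0497; adjusted p = 0.577 with an estimated correlation), but not with median centring (adjusted p = 0.0807), the deposited values (adjusted p = 0.128) or a fit without trend (adjusted p = 0.153), nor without control replicate 1 (adjusted p = 0.113), control replicate 2 (adjusted p = 0.0757) or overexpression replicate 1 (adjusted p = 0.134). None of its genes fell without control replicate 1 and 1 fell without control replicate 2. In the deposited values 3 heat shock genes fell and 1 rose, and the list median was 0.036, or -0.23 relative to the median of all genes. Camera also called the heat shock list downward with the length correction (adjusted p = 0.0276). The median of that list was -0.26 without overexpression replicate 2. Of 19 oxidative stress genes, ctt1, the glutamate-cysteine ligase gene gcs1 (0.73), the superoxide dismutase gene sod1 (0.48) and obr1 (0.47) rose and grx1 fell, with 6 up and 1 down adjusted over the list alone. That list had a median of 0.23 and was not called (adjusted p = 0.0830). It was called without control replicate 2 (adjusted p = 0.0459), without overexpression replicate 1 (adjusted p = 0.0306) and with the length correction (adjusted p = 0.0276), and with all arrays had an adjusted p = 0.577 with an estimated correlation. Without control replicate 1 its median was 0.022, without overexpression replicate 2 it was 0.14, and in neither of the fits without a control replicate did any of its genes pass. With the deposited values 9 of them rose and 1 fell.

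Of 10 nitrogen starvation and uptake genes, 7 rose, both over all genes and adjusted over the list alone, and none fell, with a median of 0.65. They included isp4 (1.21 ± 0.15 SE, limma adjusted p = 0.00415), an oligopeptide transporter gene that lies beside atf1. Also among them were isp7 (1.18), above background on only 1 control array, and the amino acid permease genes isp5 (0.83) and per1 (0.52). Camera called this list upward (adjusted p = 0.000806; adjusted p = 0.462 with an estimated correlation). Of its genes, 1 passed without control replicate 1, 2 passed without control replicate 2, and 3 passed without overexpression replicate 1 and without overexpression replicate 2, while 9 rose with the deposited values. Of 15 glucose-repressed genes, 7 rose and 3 fell, with 9 and 4 adjusted over the list alone and a median of 0.49, or 0.30 without overexpression replicate 2. Here adh4 (1.49) and the hexose transporter genes ght3 (0.98) and ght5 (0.82) rose, while ght1 (-0.83), the glycerol dehydrogenase gene gld1 (-0.68) and ght8 (-0.34) fell. The list was called upward (adjusted p = 0.0271; adjusted p = 0.577 with an estimated correlation), but not with median centring (adjusted p = 0.0680) or the deposited values (adjusted p = 0.218), and 2 of its genes rose without control replicate 1 and 2 without control replicate 2. With the deposited values 10 of these genes rose and 2 fell. Of 8 thiamine-regulated genes, nmt1 (0.70), bsu1 (0.51) and pho4 (0.43) rose and none fell, with 5 up adjusted over the list alone and a median of 0.35. Their call (adjusted p = 0.0433; adjusted p = 0.462 with an estimated correlation) was lost with median centring (adjusted p = 0.237), the deposited values (adjusted p = 0.210), a fit without trend (adjusted p = 0.0545) and without control replicate 2 (adjusted p = 0.0746), and without control replicate 1 none of its genes passed, without control replicate 2 or overexpression replicate 2 only 1. Of 12 glycolytic genes, the enolase gene eno102 (1.08) and pfk1 (0.44) rose and adh1 (-0.83) and hxk2 (-0.33) fell. Adjusted over the list alone 2 rose and 3 fell, and the list was not called (adjusted p = 0.918). Without overexpression replicate 1, 6 glycolytic genes rose and 3 fell, and without overexpression replicate 2, 2 rose and 6 fell.

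Of 22 mating genes, 6 rose, 2 fell and 14 did not pass, with 10 and 5 adjusted over the list alone and a median of 0.24. The regulator of G-protein signalling rgs1 (1.16), ste11 (0.82) and the pheromone-receptor G-protein gene gpa1 (0.75) rose, while the M-factor gene mfm2 (-0.47) and the kinase gene byr2 (-0.52) fell. Of 21 genes of meiosis and sporulation, 6 fell, 1 rose and 14 did not pass, with 8 down and 1 up adjusted over the list alone and a median of -0.39, or -0.24 without control replicate 1. The recombination genes dmc1 (-1.21), mcp7 (-1.12) and meu13 (-0.99), the cyclin gene crs1 (-1.09), the forkhead factor gene mei4 (-0.79) and rec6 (-0.56) fell, and the spore wall gene isp3 (0.81) rose. The kinase gene mek1 stood at -1.36 (adjusted p = 0.0521). Neither list was called (adjusted p = 0.141 and 0.0526), and a difference between the lists was not tested. Camera called the meiosis list downward without the background filter (adjusted p = 0.0345) and with the length correction (adjusted p = 0.0353). It did so too with the background at the 75th percentile (adjusted p = 0.0359), but not at the 99th (adjusted p = 0.0923). The adjusted p of this list was 0.462 with an estimated correlation. Its median was -0.46 without control replicate 2 and -0.15 with log2(value + 16), where camera did not call it (adjusted p = 0.0555). With the deposited values 12 mating genes rose and 1 fell, and 4 meiotic genes rose and 3 fell. In the deposited values the meiosis median was 0.09, or -0.18 relative to all genes.

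**Figure D3:**
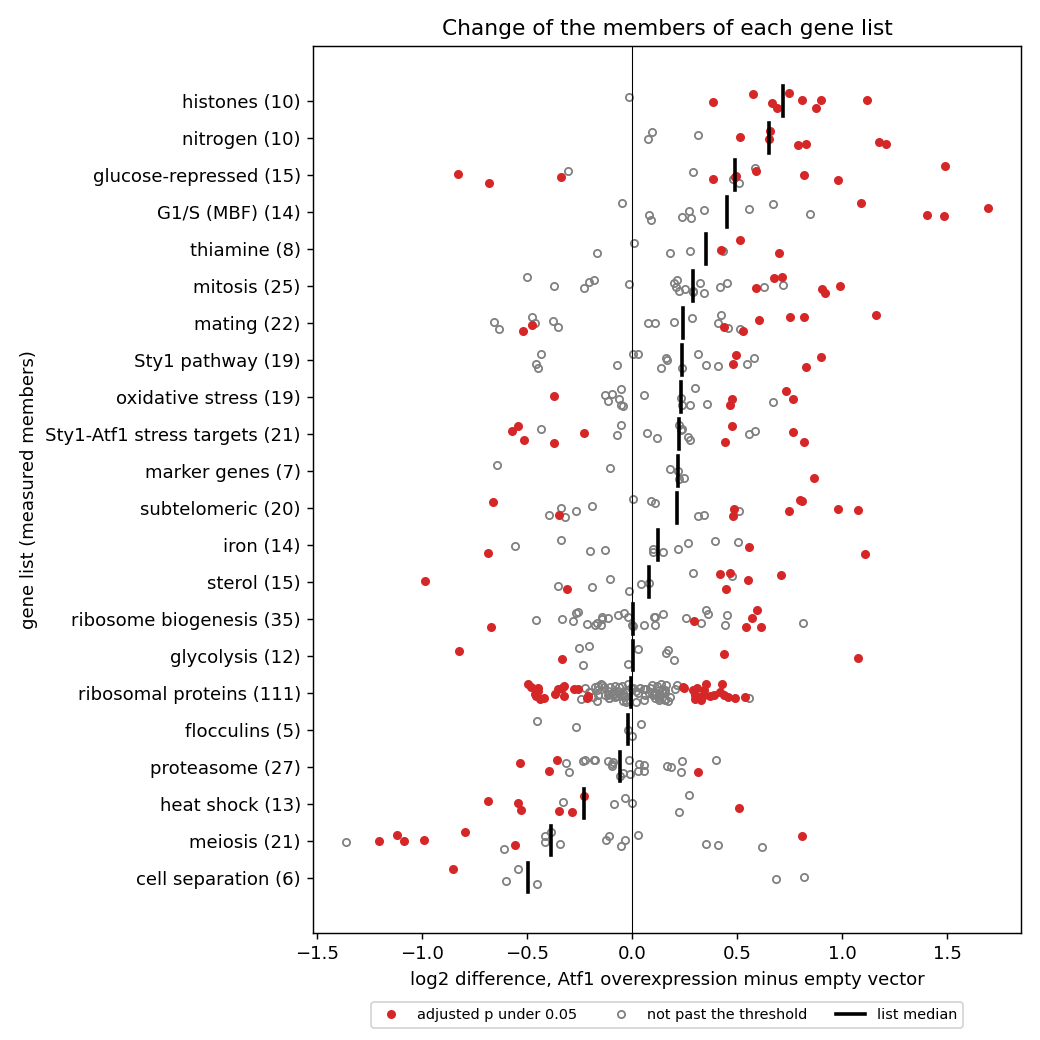
Log2 difference, Atf1 overexpression minus empty vector (horizontal axis), of each measured member of 22 gene lists (vertical axis, members in brackets), with filled points for genes with an adjusted p under 0.05, open points for the others and black lines for list medians. The histone median was 0.72, that of the nitrogen list 0.65 and that of the meiosis list -0.39, the last being 0.09 in the deposited values.

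The largest list, 111 ribosomal protein genes, was not called as a whole. Of its members 19 rose and 18 fell, or 21 and 19 adjusted over the list alone, with a median of -0.00, a mean of 0.01 and an adjusted p of 0.694. These counts turned on single arrays: 32 rose and 45 fell without overexpression replicate 1, 33 rose and 25 fell without overexpression replicate 2, none passed without control replicate 1 and 1 fell without control replicate 2. For ribosomal protein genes the deposited values gave 47 risers, 8 fallers and a median of 0.15, or -0.12 relative to all genes, and the length correction, an alternative added after the data were seen, called them upward with 31 risers and 11 fallers (adjusted p = 0.00196; without that correction adjusted p = 0.933 with an estimated correlation). Of 35 ribosome biogenesis genes, nop16 (0.61), utp20 (0.60), gar1 (0.57), bms1 (0.54) and cbf5 (0.29) rose and utp23 (-0.67) fell, the same numbers, 5 and 1, as adjusted over the list alone (list adjusted p = 0.392). Of 27 proteasome genes, rpn3 (-0.53), pre8 (-0.39) and rpn7 (-0.36) fell and rpt6 (0.32) rose, with 3 and 1 adjusted over the list alone (list adjusted p = 0.392), but with the deposited values 5 proteasome genes rose and 1 fell, and with the length correction 3 rose and 3 fell. Of 15 sterol genes, erg24 (0.71), hmg1 (0.55), erg5 (0.46), scp1 (0.45) and sre1 (0.42) rose and erg31 (-0.98) and erg1 (-0.31) fell, with 6 and 2 adjusted over the list alone (list adjusted p = 0.255). Of 14 iron genes, the siderophore transporter gene str1 (1.11) and the transporter gene abc3 (0.56) rose and the siderophore synthesis gene sib2 (-0.68) fell, also adjusted over the list alone (list adjusted p = 0.392). Of 20 subtelomeric genes, 7 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.102). These included eno102, ght3 and the galactose genes gal1 (0.80), gal7 (0.48) and gal10 (0.48), while pcm2 (-0.66) and prt2 (-0.35) fell. None of 5 flocculation genes passed, also adjusted over the list alone (list adjusted p = 0.632). Of 7 nutritional marker genes arg3 (0.87) rose and none passed adjusted over the list alone (list adjusted p = 0.370), and neither of 2 measured phosphate genes passed. With the deposited values 12 ribosome biogenesis, 7 sterol, 6 iron, 10 subtelomeric and 5 marker genes rose and none fell. Without control replicate 1, and likewise without control replicate 2, no ribosome biogenesis, proteasome, sterol or iron gene passed, while 4 and 3 subtelomeric genes rose and none fell.

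Over the 22 lists tested, camera called 8, of which 7 were upward. With an estimated correlation none was called, and the lowest adjusted p was 0.462 with an estimated correlation. With 2 arrays per group that test has few residual degrees of freedom, so this does not show that correlation between genes made the calls. For mitosis the estimated correlation was -0.025, below the preset 0.01, yet the unadjusted camera p went from 0.0033 to 0.082. For histones the estimated correlation was 0.54, so both may count there. With fry none was called either, and its lowest adjusted p was 0.0563.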

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

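In this part the tests of the control probe sets with and without a floor, the batch, the plasmid level and the scaling of atf1 were chosen only after the result was seen, while the tests of scaling and length on the gene lists were set down before those tests were run, when deposited values of single genes had been seen.

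The S. cerevisiae LEU2 probe set gave signal on an array set of S. pombe samples, ranking 1 among S. cerevisiae probe sets. Its deposited log2 values were 12.3 and 12.3 in the control and 12.7 and 12.8 under overexpression, a difference of 0.47, while ARP2, the next highest, stood at 5.13 and 4.38 and URA3 at 2.58 and 2.12. LEU2 is a common plasmid marker in fission yeast. For the atf1 rise, the lowest difference over 3 scalings was 0.83 ± 0.20 (SE), so the rise did not rest on the choice among these. No scaling to the added controls was tried. Poly-A middle probe sets shifted by 1.22, against an atf1 difference of 1.10 in the deposited values, and hybridization controls shifted by -1.02. Between-array scaling as a whole is therefore not excluded. A higher plasmid level stays open: relative to the median shift of S. pombe probe sets LEU2 stood 0.24 higher, but by the labels the control vector was empty, so a marker present in both groups and atf1 need not rise alike, and a lower LEU2 value excludes nothing.

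The added control probe sets separated the groups. Poly-A controls at the 5′ end had a mean shift of 1.56 under overexpression and hybridization controls were lower, but 6 of the 12 poly-A 5′ probe sets were at background on both control arrays, so with values below background raised to it the shift was 1.27, a lower bound. The poly-A 5′ and hybridization shifts lay 2.58 apart as measured and at least 2.30 apart with that floor, and the poly-A middle probe sets, all above background on every array, lay 2.24 from the hybridization controls, so 1 scale factor per array could not give both. Longer labelled fragments would narrow the gap between 5′ and 3′ probe sets, and with the floor this gap changed by at least 0.93 ± 0.19 (SE) over 12 poly-A probe set pairs. These pairs read the dap, lys, phe and thr transcripts several times each, so they are not independent and their SE is too small. Over 7 S. pombe control mRNAs the gap changed by 0.18 ± 0.23 (SE) as measured, and by 0.11 ± 0.27 (SE) with the floor over the 6 left without URA4, which was at background at both ends. Longer labelled fragments therefore stay open as an explanation. No biological explanation was tested for the added transcripts, which come from outside the cells.

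Camera called the histone, G1/S and nitrogen lists upward. At the preset correlation, all 3 lists stayed called upward with median centring and with the deposited values (3 of 3 under the less favourable scaling). The calls thus did not rest on the quantile step. These 2 scalings differ only by a constant per array. Camera compares a list with other genes, so a shift of all genes alike could hardly remove a call. All 3 lists also stayed called after the correction for gene length (3 of 3). For the G1/S and nitrogen lists, with median lengths of 2073.5 and 2170 bp, this argues against the length trend as the whole cause. Histone genes, with a median of 828 bp, were short while rising genes were longer, so the correction could hardly have removed their call. These calls did not hold with an estimated correlation (adjusted p = 0.462 with an estimated correlation for each) or with fry (adjusted p of 0.0563 for G1/S and 0.0595 for the others). A labelling or hybridization batch cannot be told apart from Atf1 overexpression, because the hybridization controls shifted by -1.02 with no overlap between groups and each group lay at its own level. A biological effect of Atf1 overexpression on these genes is therefore only 1 of the explanations that stay open.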

How the results depend on the processing

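The deposited values and the length correction were chosen after the data were seen. The planned quantile alternative equalled the setting used. Background filters, the robust fit, the mean of probe sets and the length correction kept the numbers of genes and lists within 1.5 times, and the sign of the atf1 difference was positive in every setting. Genes passing numbered 165 without trend, 932 at an adjusted p under 0.1, 5 with an ordinary t statistic, 1019 with the deposited values, and 53 to 682 with 1 array left out. At least 2-fold, 84 passed with median centring, 15 with log2(value + 16), 158 with the deposited values, and 25 to 65 with 1 array left out. Lists called were 4 with median centring, 5 without trend, 0 with an estimated correlation, 0 with fry, 4 with the deposited values, and 6 to 8 with 1 array left out. The atf1 difference was 0.83 without trend (adjusted p = 0.0704) and 0.58 to 1.14 with 1 array left out. With the replicate block, 852 genes passed, 51 at least 2-fold, 11 lists were called and atf1 had an adjusted p of 8.88e-06; same-numbered arrays shared only a number (correlation of deviations 0.038), so no pairing was used. Of the genes passing, 408 passed in the same direction with the deposited values, 535 with median centring, 162 without trend, 47 without control replicate 1 and 65 without control replicate 2. Signs reversed for wis1 (-0.046 with median centring, -0.0011 with the length correction, -0.094 to 0.144 with 1 array left out) and, with 1 array left out, for sty1 (-0.015 to 0.032), cdc13 (-0.104 to 0.081) and srk1 (-0.223 to 0.082). With the deposited values they reversed for mbx2 (0.11), pfl8 (0.17), vtc4 (0.078), cdc13 (0.20), srk1 (0.14), leu1 (0.13), clp1 (0.18) and hsp16 (0.036); of these genes hsp16 alone had passed. The deposited values raise the median of all genes by 0.27 and a looser threshold admits more genes by construction; leaving out arrays leaves fewer samples; for the other settings the cause was not tested. Of 2131 values for 143 genes followed singly, 1738 kept direction and side of the threshold, 341 lost the call, 36 gained it and 16 reversed. Signal near background limits genes such as alp7, tas3, mug62 and ura4, and also isp7 and spo12, which were above background on only 1 control array. The fhn1 value on control replicate 1, 3.27, lay close to the background of 3.25 on that array.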

Other observations

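The 9 gene groups in this part were chosen after their values were seen, and the test of adjacent genes was set down beforehand. None of these groups was called by camera (limma). Of 18 genes of heterochromatin and RNA interference, clr4 (-1.34), the Dicer gene dcr1 (-1.03) and the RNA-dependent RNA polymerase gene rdp1 (-0.52) fell, while the histone deacetylase gene clr3 (0.85) and tas3 (at least 1.73-fold) rose, with the same 3 and 2 adjusted over the list alone, and the group had a median of -0.11 (adjusted p = 0.777). Of 11 cohesin genes, psm3 (1.06) and pds5 (1.06) rose and none fell, also adjusted over the list alone, with a median of 0.41 (adjusted p = 0.138). Of 14 genes of the wtf family, which includes meiotic drivers, wtf14 (0.95), wtf17 (0.89) and wtf9 (0.85) rose and none fell. Adjusted over the list alone, 5 rose and 2 fell (camera, list adjusted p = 0.138). Related members of the family may share probe signal, which was not tested, so their values are uncertain.

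Of 39 mitochondrial ribosomal protein genes, 6 fell, including mrpl33 (-1.09) and mrpl39 (-0.92), and mrps28 (0.49) and mrpl31 (0.42) rose, with 8 down and 2 up adjusted over the list alone (adjusted p = 0.138). Of 20 Mediator genes, med6 (-1.13) and med18 (-0.56) fell and none rose, also adjusted over the list alone (adjusted p = 0.282). Of 29 kinetochore genes, mis18 (-1.07) and fta6 (-0.88) fell and none rose, but no gene passed adjusted over the list alone (adjusted p = 0.626). Of 29 replication genes, mcm3 (1.18) rose and orc5 (-0.52) fell, with 1 up and none down adjusted over the list alone (adjusted p = 0.626). Of 16 tRNA synthetase genes 2 rose and 2 fell, with 3 up and 4 down adjusted over the list alone, and of 12 vacuolar ATPase genes 2 fell and none rose, also adjusted over the list alone (adjusted p = 0.809 and 0.930).

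The nitrogen gene isp4, which rose, lies beside atf1, while the other neighbour, fic1, differed by 0.07 (adjusted p = 0.838). Likewise mug86, which rose, lies beside mug116, which fell. Whether adjacent genes change together was tested over 1648 adjacent measured pairs. Across these pairs Pearson r was 0.0212 and Spearman's rho 0.0323 (permutation p = 0.383, 10000 permutations, for Pearson's r), and genes are not independent replicates. This argues against a general tendency of neighbours to change together as the cause of the joint rise of atf1 and isp4; whether the isp4 probe set reads transcripts from this locus was not tested.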
